A study of Homo sapiens with 6 samples.

How the data were processed

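RNA from MHCC97H cells was extracted with Trizol, and libraries were prepared with the NEBNext Ultra RNA kit from total RNA, per the labels' protocols. There were 3 samples of each of 2 groups, shcontrol and shHNRNPC. The design text of the series calls the experiment a microarray, while the series type and the deposited counts are those of sequencing. The labels describe 1 cell line and tell apart 1 knockdown construct.

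The submitters' processing notes name STAR, HTSeq 0.6.0 and DESeq2, with no version for STAR and DESeq2. The genome build, the annotation and the use of strand in counting are not given in the sources used here. The deposited read counts are whole numbers per gene and library that the authors had not normalised. The log2 fold changes in the deposited table are the authors' own, of SI over NC. The p-values and adjusted p-values in the deposited table are also the authors' own, and their adjustment method is not stated in the file headers. A shorter deposited table repeats the 6194 genes with the authors' adjusted p under 0.05. The columns are named NC and SI and were assigned to shcontrol and shHNRNPC as groups by these names. Their suffixes do not give the replicate number of the sample titles, so no column was tied to a single sample. Another 24 columns of per-library values (normalised counts, FPKM and repeated counts) were not used. Every row of the table carries a gene name. The type column marks 15211 rows as mRNA and leaves 387 blank, so no gene is marked as non-coding and none was named for that reason.

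Of the 15598 gene names, all occur in GENCODE 29. Among the 15211 genes with a position in the deposited table, 96.1% overlap the gene of that name in GENCODE 29, which uses GRCh38. Positions are printed as the deposited table gives them. Transcript GC content and length came from the longest coding transcript in GENCODE 29 and were found for 11831 of 11831 tested genes. Which transcripts these cells express was not determined. The values used for the GC and length correction and for matched lists can therefore differ from those of the expressed transcripts.

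Counts were analysed in R 4.3.3. Low counts were removed with filterByExpr by group, libraries were scaled by TMM, and groups were compared with glmQLFit and glmQLFTest in edgeR 4.0.16, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken from the fold change and the test statistic. Gene lists were tested on voom values with camera at a preset correlation of 0.01, with an estimated correlation, and with fry in limma 3.58.1, with adjustment over the 26 lists tested. The lists, tests and alternatives were fixed before the data were examined, except where stated. The lists covered the hnRNP family, splicing factors, type I interferon response, double-stranded RNA sensing, MHC class I antigen presentation, NF-kB targets, m6A factors, S phase, G2 and mitosis, p53 targets, epithelial, mesenchymal and hepatocyte genes, RAS-MAPK output, hypoxia and glycolysis, cholesterol biosynthesis, the unfolded protein and integrated stress response, heat shock, collagens and matrix, ribosomal proteins, mitochondrially encoded genes, zinc finger genes, histones, and markers of fibroblasts, leukocytes, endothelium and other epithelia.

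Genes were named by a rule. It took HNRNPC, the 12 highest and 12 lowest fold changes among mRNA rows past the threshold with a mean of at least 5 CPM and no overlap between groups, the 4 most abundant genes changed at least 2-fold in each direction, and up to 4 members of each list with the smallest adjusted p. For a list with no member past the threshold it took the 2 most abundant. Some genes that the rule takes are not reported here.

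Replicates were checked against counting noise over genes with at least 20 counts in a pair of libraries. Chi-square per gene was 1.56 to 2.50 within groups, where 1 is expected for counting noise alone, and 29.5 to 33.7 between groups. No pair was therefore counted as the same library. Depth was similar in the 6 libraries, and the 10 most counted genes took 5.60% to 5.77% of the counts.

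The scripts were tested on simulated counts for this comparison with 200 changed genes. The edgeR fit, run on 11836 genes, recovered 82.1% of 1.25-fold, 92.5% of 1.5-fold and 98.5% of 2-fold changes, with 12 false calls. In the data 7228 of 11831 tested genes were called. The recovery and false calls therefore hold for far fewer changed genes, simulated with 1 dispersion, and do not measure error in the real comparison. With no gene changed, 0 lists passed camera. With the 200 changed genes, drawn at random without regard to the lists, 2 lists passed, and 3 passed when the interferon list was also raised 1.25-fold, that list among them. Genes were simulated independently of each other, so these list results do not show how camera at the preset correlation behaves when genes are correlated.

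Alternatives were other scalings (RLE, upper quartile, library size alone), no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, mRNA rows only, a test against a 1.5-fold change, an estimated correlation, and leaving out each library. Added after the data were examined were a replicate block from the column suffixes and a correction that removed splines (4 degrees of freedom each) of GC content and log2 transcript length from each library. Another 6 gene lists were also written then. For the calls shared with the authors' deposited table only the DESeq2 alternative had been fixed beforehand, and the others were added. Counting can lose reads of genes with overlapping or duplicated models: ZYX had at most 1 count in any library and U2AF1 at most 15, and values of such genes are uncertain, as are values of genes that overlap others on either strand.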

Results

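Gene expression was measured by RNA sequencing in MHCC97H cells, a hepatocellular carcinoma line known for its high metastatic capacity. HNRNPC encodes hnRNP C, a nuclear protein that binds uridine-rich stretches of nascent transcripts and takes part in splice site choice. The series compared 3 libraries of cells carrying a short hairpin RNA against HNRNPC (shHNRNPC) with 3 libraries of cells carrying a control hairpin (shcontrol). The question was which genes change when HNRNPC is knocked down. The deposited table held read counts for 15598 genes. Total counts were 16819724, 15563077 and 18328475 in the shcontrol libraries NC_3, NC_3_2 and NC_3_3, and 16692497, 17798104 and 17889820 in the shHNRNPC libraries SI_3, SI_3_2 and SI_3_3. After filtering, 11831 genes were tested. Levels are read counts scaled to library size (CPM), as mean ± SD with n = 3 per group, and fold changes are shHNRNPC over shcontrol with adjusted p-values from edgeR's quasi-likelihood test.

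The targeted transcript was lower in every shHNRNPC library. HNRNPC, placed by the deposited table at chromosome 14, 21209136 to 21269494, on the minus strand, had 14409, 13507 and 15908 counts in the shcontrol libraries and 1010, 1164 and 1042 in the shHNRNPC libraries. Its level fell from 853 ± 4.76 CPM to 62.3 ± 3.80 CPM, a log2 fold change of -3.77 (SE 0.030, adjusted p = 5.04e-55), which left 7.30% of the shcontrol level. The authors' deposited table gives -3.77 for the same gene. It was the most strongly decreased of the 12 genes with the largest falls.

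In the knocked-down cells the largest increases included interferon-stimulated genes, and the largest falls included HIF1A, ARCN1, PRMT3 and WRNIP1. TRIM22, an interferon-induced ubiquitin ligase, rose 6.29-fold, from 3.66 ± 0.429 to 22.96 ± 1.42 CPM. RSAD2, the antiviral enzyme viperin, rose 4.46-fold, from 26.8 ± 2.33 to 119 ± 2.29 CPM. HIF1A, the oxygen-regulated subunit of a hypoxia transcription factor, fell 4.02-fold, from 110 ± 1.84 to 27.5 ± 0.934 CPM. ARCN1, the delta subunit of the COPI vesicle coat, fell 3.62-fold, from 263 ± 5.82 to 72.6 ± 3.58 CPM.

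Across all tested genes, 3520 had higher and 3708 had lower counts in shHNRNPC. Most changes were small. Of the 7228 genes called, 5569 changed by less than 1.5-fold, whereas 221 rose and 187 fell by at least 2-fold. Tested against a 1.5-fold change instead of no change, 217 genes were higher and 391 lower. The number at least 2-fold higher was 144 when genes under a mean of 1 CPM were left out. The number at least 2-fold lower was 116 after a correction for transcript GC content and length that was chosen after the data were examined.

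**Figure D1:**
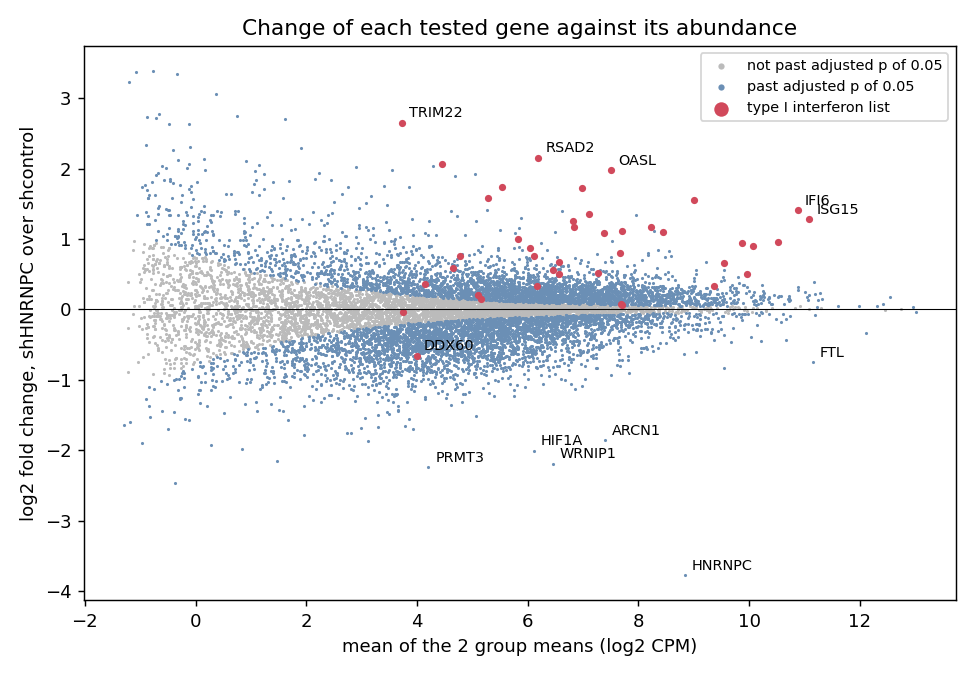
Log2 fold change of each tested gene (vertical axis, shHNRNPC over shcontrol) against its mean abundance (horizontal axis, log2 CPM), with genes past an adjusted p of 0.05 in blue, the others in grey and the type I interferon list in red. HNRNPC lies at -3.77, and 39 of the 41 interferon genes were called higher.

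The other genes with the largest rises included further interferon-induced genes and several outside that group. OASL, an oligoadenylate synthetase-like protein, rose 3.94-fold (74.0 ± 1.30 to 291 ± 2.11 CPM). ISG20, an exonuclease acting on single-stranded RNA, rose 4.18-fold. DHX58, the RNA helicase LGP2 that binds viral double-stranded RNA, rose 3.80-fold. RTP4 rose 4.06-fold, HSH2D 3.56-fold and RARRES3 3.71-fold. CEACAM1, a cell adhesion receptor, rose 4.12-fold, from 7.62 ± 0.255 to 31.4 ± 0.108 CPM. RHEBL1, a small GTPase, rose 3.93-fold. The zinc finger gene ZNF684 rose 3.38-fold and AMH, which encodes anti-Müllerian hormone, rose 3.34-fold. All of these passed an adjusted p of 0.05 with no overlap between the 3 values of each group.

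Among the largest falls, PRMT3, an arginine methyltransferase that acts on a ribosomal protein, fell 4.73-fold, from 30.3 ± 1.27 to 6.42 ± 0.959 CPM. WRNIP1, an ATPase that binds the Werner helicase, fell 4.57-fold, from 144 ± 2.45 to 31.5 ± 0.836 CPM. WRN, the Werner helicase itself, fell 3.39-fold, and RAD18, a ubiquitin ligase of post-replication repair, fell 3.15-fold. SLC46A3, SLC25A40 and SLC9A2, members of solute carrier families, fell 3.67-fold, 3.20-fold and 3.19-fold. NEXN, an actin-binding protein, fell 3.37-fold and CDYL2, a chromodomain protein, fell 3.25-fold. In the deposited table WRNIP1 lies on chromosome 6, 2766052 to 2786952, PRMT3 on chromosome 11, 20387530 to 20509253, HIF1A on chromosome 14, 61695540 to 61748258, and ARCN1 on chromosome 11, 118572436 to 118603033, each on the plus strand.

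The most abundant genes with at least a 2-fold rise were ISG15 (1271 ± 33.4 to 3094 ± 16.3 CPM), a ubiquitin-like modifier, IFI6 (1029 ± 114 to 2741 ± 20.6 CPM), OAS2 (259 ± 10.3 to 765 ± 10.1 CPM) and OAS1 (223 ± 5.63 to 478 ± 2.78 CPM). The most abundant with at least a 2-fold fall included HNRNPC, ARCN1 and XPO1, the nuclear export receptor (172 ± 1.68 to 80.5 ± 1.21 CPM). OAS1 and OAS2 lie on chromosome 12, at 112906850 to 112918462 and 112978590 to 113011216.

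**Figure D2:**
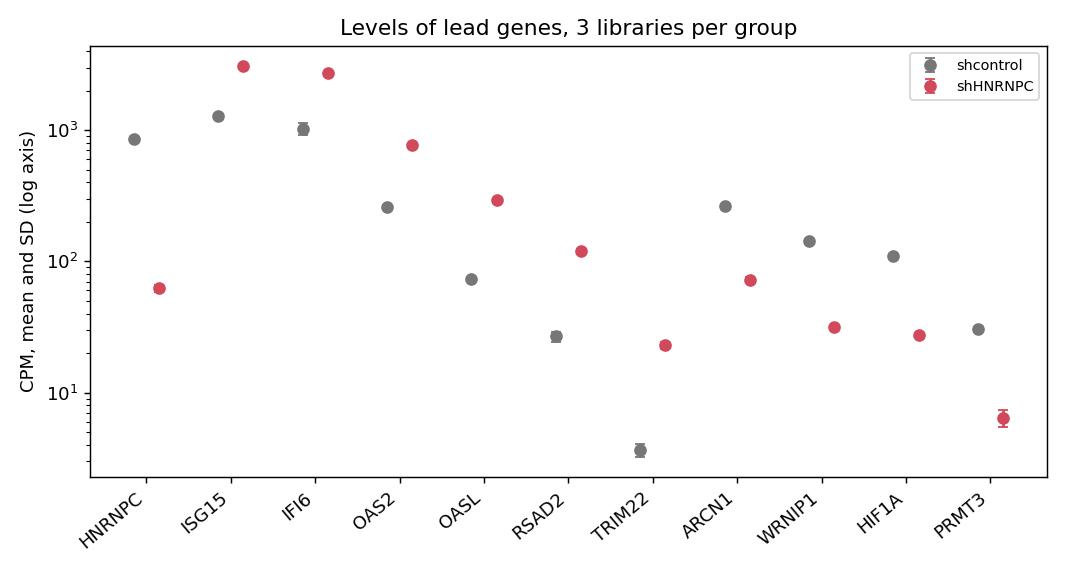
Scaled read counts in CPM (log axis, mean with SD over 3 libraries) of HNRNPC, 6 genes that rose and 4 that fell, shcontrol in grey and shHNRNPC in red. TRIM22 went from 3.66 to 22.96 CPM and HIF1A from 110 to 27.5 CPM, and the bars of the groups do not overlap.

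Before the data were examined, 27 gene lists were fixed, of which 26 had at least 3 tested members. By camera, a competitive test that compares a list with all other genes, 6 lists were higher and 3 were lower at an adjusted p under 0.05 with a preset correlation between genes of 0.01. With a correlation estimated from the 6 libraries, 1 list kept its call, the type I interferon response.

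Of the 41 tested type I interferon genes, 39 rose and 1 fell, and the counts adjusted over the list alone were also 39 and 1. The median log2 fold change was 0.90, and 17 genes rose at least 2-fold (camera adjusted p = 2.59e-32, and adjusted p = 0.0149 with an estimated correlation). By fry, which tests a list's own direction without comparing it with other genes, the p was 3.96e-08. MX1, a dynamin-like antiviral GTPase, rose 1.93-fold to 1931 ± 28.6 CPM. The gene that fell was DDX60, an RNA helicase with a log2 fold change of -0.66 (SE 0.086), and SAMD9 was the gene that did not pass. Both were named after their values were seen. The median was 0.83 after the GC and length correction.

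Genes of double-stranded RNA sensing were higher as a list, with 8 of 14 rising, 2 falling and a median of 0.37 (adjusted p = 0.00677, and adjusted p = 0.196 with an estimated correlation). The counts adjusted over the list alone were also 8 and 2. Besides DHX58, ADAR, the adenosine deaminase that edits double-stranded RNA, rose 1.37-fold to 1035 ± 8.42 CPM, TRIM25 rose 1.22-fold and IRF3, a transcription factor of interferon genes, rose 1.38-fold. MHC class I antigen presentation had 11 of 12 genes higher and 0 lower, by both adjustments over all genes and adjusted over the list alone, with a median of 0.36 (adjusted p = 2.14e-06, and adjusted p = 0.0721 with an estimated correlation). B2M, the light chain of class I molecules, rose 1.80-fold, from 233 ± 7.80 to 419 ± 23.5 CPM. The chaperones CALR and PDIA3 rose 1.31-fold and 1.24-fold. Counts of class I heavy chain genes are uncertain because reads can match more than 1 family member.

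Among 33 genes of G2 and mitosis, 21 fell and 7 rose, also when adjusted over the list alone, and the median was -0.23 (adjusted p = 6.20e-04, and adjusted p = 0.196 with an estimated correlation). This median lay at percentile 2.99 of 10000 random lists matched on GC content and transcript length, inside their central 95% range (-0.238 to 0.067), a comparison added after the data were examined. After the GC and length correction the median was -0.24 (adjusted p = 9.88e-04). AURKA, a mitotic kinase, fell 1.46-fold to 215 ± 1.71 CPM. TOP2A, the topoisomerase of mitotic chromosomes, fell 1.58-fold, ECT2, which directs cytokinesis, fell 1.66-fold, and CENPF, a kinetochore protein, fell 1.79-fold. The S phase list did not pass (14 of 35 higher, 11 lower, adjusted p = 0.741). After the GC and length correction 12 of its genes were higher and 15 lower, and its median turned from 0.050 to -0.044. As counted, MCM3 of that list fell 1.91-fold and MCM4 fell 1.31-fold. MCM7, another subunit of the same replicative helicase, rose 1.27-fold and CDT1, a licensing factor, rose 1.47-fold. Both cell cycle lists had the same uncorrected counts adjusted over the list alone.

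Of 18 m6A writers, erasers and readers, 12 fell and 2 rose, with the same counts adjusted over the list alone and a median of -0.25 (adjusted p = 0.00395, and adjusted p = 0.156 with an estimated correlation). IGF2BP2, a reader of methylated mRNA, fell 1.46-fold to 83.8 ± 1.04 CPM. VIRMA and ZC3H13, subunits of the methyltransferase complex, fell 1.60-fold and 1.52-fold, and the reader YTHDC2 fell 1.64-fold. After the GC and length correction the median was -0.20 (adjusted p = 0.0325). The uncorrected median lay at percentile 7.71 of matched random lists, inside their central 95% range (-0.318 to 0.073).

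Cholesterol biosynthesis genes were higher as a list, with 15 of 24 rising and 4 falling, also when adjusted over the list alone, and a median of 0.19 (adjusted p = 0.00104, and adjusted p = 0.156 with an estimated correlation). The enzymes MSMO1, FDPS and ACAT2 rose 1.66-fold, 1.23-fold and 1.32-fold. The median was 0.12 after the GC and length correction (adjusted p = 0.00210). Of 27 genes of the unfolded protein and integrated stress response, 18 rose and 6 fell, with the same counts adjusted over the list alone and a median of 0.20 (adjusted p = 0.00953, and adjusted p = 0.201 with an estimated correlation). ATF4, the transcription factor of the integrated stress response, rose 1.51-fold to 388 ± 5.23 CPM and NUPR1 rose 1.63-fold. HSP90B1, a chaperone of the endoplasmic reticulum, fell 1.23-fold, and the cystine transporter SLC7A11 fell 2.23-fold. After the GC and length correction the median of this list was 0.06 (adjusted p = 0.116).

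Cytoplasmic ribosomal protein genes rose in 61 of 75 cases and fell in 2, and in 62 and 4 cases when adjusted over the list alone, by small amounts (median 0.18, adjusted p = 7.53e-18, and adjusted p = 0.196 with an estimated correlation). RPLP1 and RPS12 rose 1.27-fold and 1.41-fold, RPL30 rose from 715 ± 14.5 to 894 ± 13.3 CPM and RPL37A from 890 ± 30.2 to 1108 ± 21.3 CPM. The longest annotated coding transcripts of these genes are short, with a median of 1197 bases. After the GC and length correction 33 rose and 28 fell, and the median log2 fold change was 0.03 (adjusted p = 0.0611). Reads of ribosomal protein genes can be shared with their processed pseudogenes. Of 12 mitochondrially encoded genes, 9 fell and 1 rose, also when adjusted over the list alone, with a median of -0.12 (adjusted p = 0.00338, and adjusted p = 0.226 with an estimated correlation). MT-CO3 fell 1.35-fold to 1387 ± 28.4 CPM, MT-ATP6 fell 1.21-fold and MT-CYB fell 1.22-fold, while MT-ND1 rose 1.13-fold and lost its call after the GC and length correction (log2 fold change -0.0039).

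**Figure D3:**
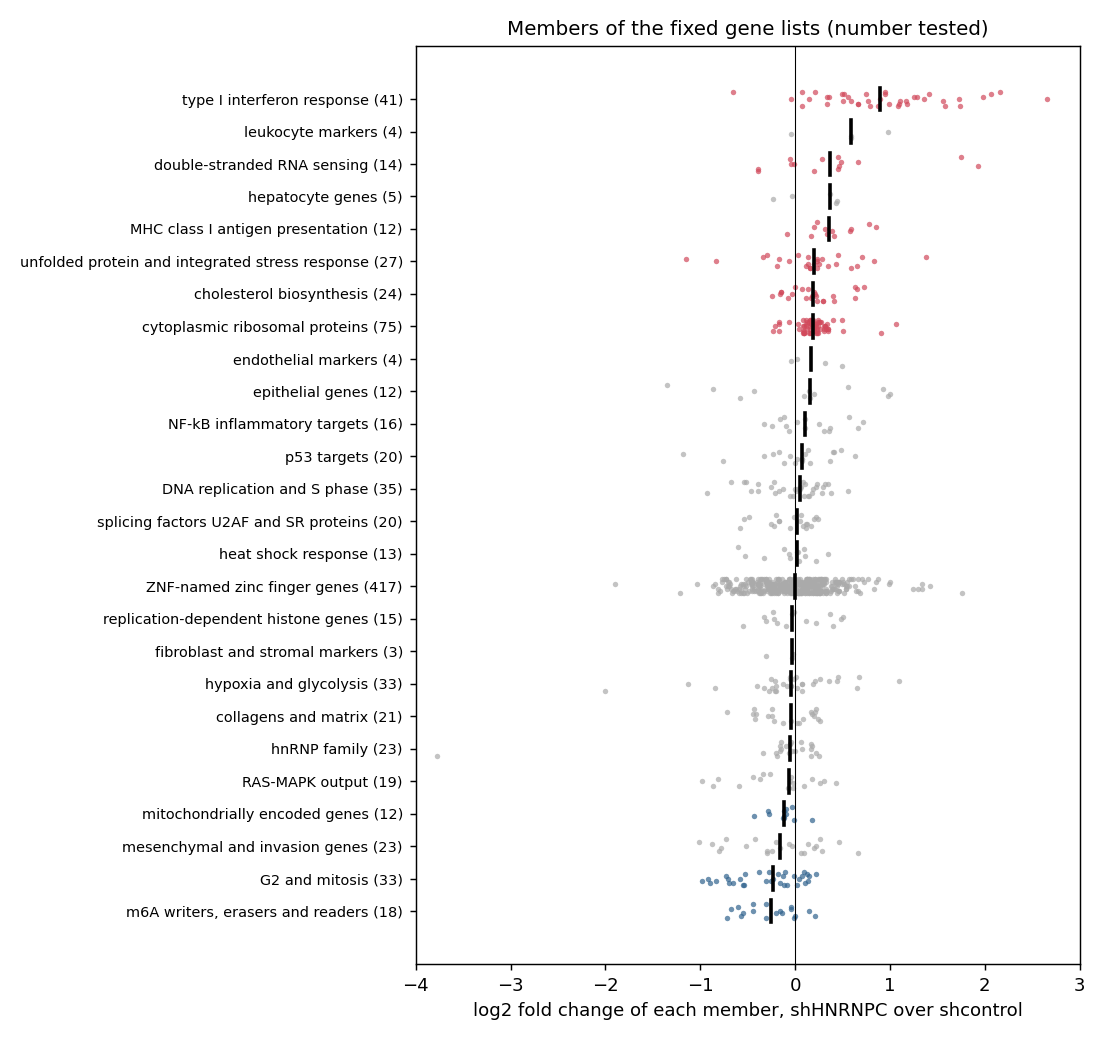
Log2 fold change of each tested member (points, shHNRNPC over shcontrol) of the 26 lists, with a black bar at the median, red for lists higher and blue for lists lower by camera at the preset correlation, and grey for the others. The medians run from 0.90 for the type I interferon genes to -0.25 for the m6A genes.

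The remaining lists did not pass the competitive test as counted, although single members changed. In the hnRNP family 7 of 23 genes rose and 12 fell (13 adjusted over the list alone). After the GC and length correction 12 rose and 7 fell, and the median turned from -0.049 to 0.105 (camera adjusted p = 0.407). Apart from HNRNPC the changes as counted were small. They included a 1.16-fold rise of HNRNPF, a 1.19-fold rise of HNRNPDL and a 1.26-fold fall of SYNCRIP. SYNCRIP lost its call after the correction (log2 fold change 0.077). Among 20 splicing factors 8 rose and 8 fell, among them a 1.49-fold fall of SF3B1, a 1.46-fold fall of SRSF11, a 1.40-fold fall of U2SURP and a 1.18-fold rise of SRSF3. U2SURP lost its call after the GC and length correction (log2 fold change -0.057, adjusted p = 0.260). The median of that list was 0.02 while camera pointed down (adjusted p = 0.748). In the hypoxia and glycolysis list 11 of 33 rose and 12 fell, with a median of -0.039. After the GC and length correction 8 rose and 17 fell, and the list was called lower (median -0.169, adjusted p = 0.0149). HIF1A fell, EGLN1, a prolyl hydroxylase that marks HIF1A protein for degradation, fell 1.79-fold, and P4HA2 and PGAM1 rose 1.37-fold and 1.20-fold. Of 19 genes of RAS-MAPK output 8 fell and 1 rose (median -0.068, adjusted p = 0.0795). After the GC and length correction 11 fell and 0 rose, and the list was called lower (median -0.154, adjusted p = 0.0281). The correction also moved the median of all tested genes from -0.004 to -0.049, so counts and medians after it lean lower. As counted there were falls of 1.82-fold for EPHA2, 1.30-fold for HBEGF and 1.75-fold for SPRY4, and DUSP5 fell from 39.8 ± 1.78 to 26.5 ± 0.289 CPM. The splicing, hypoxia and RAS-MAPK lists had the same counts adjusted over the list alone.

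Of 23 mesenchymal and invasion genes, 13 fell and 7 rose. S100A4, a calcium-binding protein linked to metastasis, fell 1.71-fold to 44.4 ± 1.12 CPM, whereas PLAUR, the urokinase receptor, rose 1.59-fold, ITGA5 rose 1.38-fold and SPARC rose 1.21-fold. Of 12 epithelial genes 6 rose and 4 fell, with rises of CLDN4 (1.47-fold), KRT8 (1.15-fold) and JUP (3.51 ± 0.183 to 7.06 ± 1.32 CPM) and a 1.35-fold fall of PKP2. After the GC and length correction 3 epithelial genes rose and 4 fell (median -0.025, from 0.155), and KRT8 lost its call (log2 fold change 0.018). Of 21 genes of collagens and matrix 6 rose and 9 fell, and CTGF, CYR61, HSPG2 and COL12A1 fell 1.64-fold, 1.36-fold, 1.35-fold and 1.34-fold. Among 16 NF-kB targets 6 rose and 2 fell, including rises of CSF1 (1.59-fold), ICAM1 (1.48-fold), SOD2 (1.28-fold) and NFKB2 (1.19-fold). Of 20 p53 targets 6 rose and 4 fell, with TNFRSF10B and BBC3 up 1.40-fold and 1.54-fold and MDM2 and ZMAT3 down 1.69-fold and 2.27-fold. In the heat shock list 4 of 13 rose and 4 fell, with HSP90AA1 and HSPH1 down 1.52-fold and 1.45-fold and HSP90AB1 and HSPB1 up 1.17-fold and 1.27-fold. After the GC and length correction 5 p53 targets rose and 7 fell (median -0.098, from 0.071). Mesenchymal genes then had 4 higher and 15 lower, heat shock genes 3 and 7, matrix genes 4 and 9, and NF-kB targets 7 and 5. As counted, each of these lists gave the same counts adjusted over the list alone.

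Of 417 zinc finger genes with a ZNF symbol, 89 rose and 79 fell (83 and 77 adjusted over the list alone). ZNF738 rose 2.67-fold, while ZNF106 and ZNF664 fell 1.76-fold and 1.59-fold. Of 15 replication-dependent histone genes 2 rose and 0 fell, HIST1H2BK by 1.16-fold and HIST1H4I by 1.29-fold. After the GC and length correction 1 rose and 2 fell, and HIST1H2BK was called lower (log2 fold change -0.13, adjusted p = 0.00936). Of the hepatocyte genes 5 passed the filter on low counts and 1 of them, CPS1, rose 1.29-fold to 33.5 ± 2.02 CPM. Of 4 leukocyte markers 1 rose, CD68 (43.2 ± 3.64 to 64.9 ± 2.12 CPM). Of 3 fibroblast and stromal markers 1 fell, ACTA2, at 1.24-fold, and of 4 endothelial markers 1 rose, EGFL7 (53.3 ± 1.41 to 66.4 ± 2.15 CPM), which lost its call after the GC and length correction (log2 fold change 0.066). The histone, hepatocyte and marker lists had the same counts adjusted over the list alone. Lineage markers of intestine and other epithelia had 2 members that passed the filter on low counts and were not tested.

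Fold changes followed the sequence of the transcripts. Across genes, Spearman's rho of the log2 fold change was 0.43 with transcript GC content and -0.32 with transcript length, where genes are not independent replicates. In the tenth of genes with the lowest GC content (30.2% to 38.7%) the median log2 fold change was -0.40, with 766 genes lower and 69 higher, and in the tenth with the highest (62.1% to 74.5%) it was 0.12, with 153 lower and 517 higher. Among the 9 lists called by camera, the medians of G2 and mitosis and of the m6A genes lay inside the central 95% range of random lists matched on GC content and transcript length, and those of the others lay outside it. The median of the ribosomal proteins lay just outside (0.185 against a limit of 0.181). The GC and length correction sorted these lists otherwise. Under it G2 and mitosis and the m6A genes kept their calls. Ribosomal proteins and the unfolded protein and integrated stress response lost theirs, so these checks disagree.

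**Figure D4:**
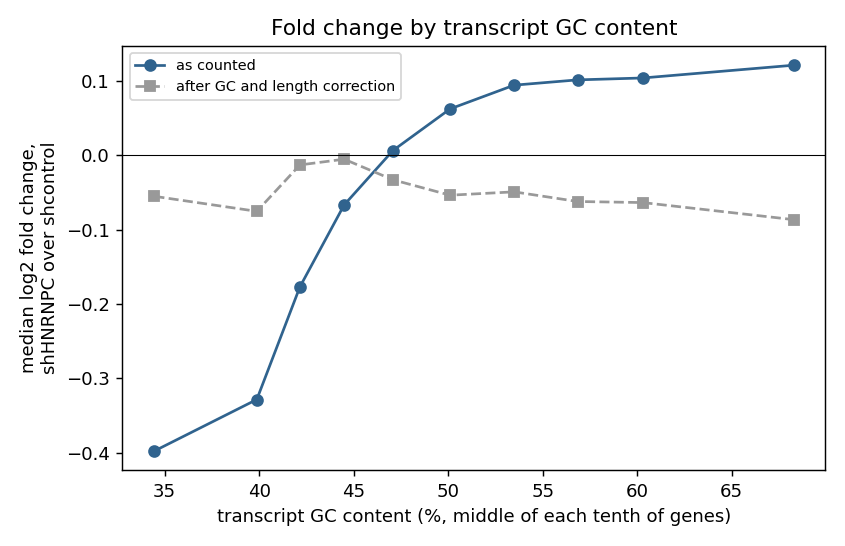
Median log2 fold change (vertical axis, shHNRNPC over shcontrol) of genes in 10 groups of about equal size by transcript GC content (horizontal axis, %), as counted (solid) and after the GC and length correction (dashed). The solid line runs from -0.40 to 0.12.

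The authors' deposited table calls 6194 genes at an adjusted p under 0.05, of which 3026 are higher and 3168 lower in the knockdown. Of these, 6140 were also called here in the same direction and 0 in the opposite one. The other 54 of the authors' calls are genes that were not tested here. A further 1088 genes were called here by edgeR and not in the authors' deposited table. With the DESeq2 Wald test, the tool the submitters name, 3011 genes were higher and 3156 lower, and 6166 calls were shared with the authors' deposited table. In edgeR without the filter on low counts 6193 calls were shared, so the 54 missed calls go mostly with the filter. That setting still called 3614 genes higher and 3651 lower, so the further calls go mostly with the choice of tool. What made the replicates independent is not described in the sources used here, so the p-values measure only the spread between these libraries, which may be technical. That spread was small, with a common biological coefficient of variation of 2.47%.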

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

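The GC and length correction and the replicate block were chosen after the data were examined, as were all alternatives but DESeq2 for calls shared with the authors. HNRNPC, the counts of called genes and the number of shared calls with the authors' deposited comparison stayed within 1.5 times their values under all alternatives except those named here. A test against a 1.5-fold change gave 217 genes higher and 391 lower, since it asks for a larger change. The filter at a mean of 1 CPM left 144 genes at least 2-fold higher, since weakly expressed genes were not tested. After the GC and length correction 116 genes were at least 2-fold lower. With an estimated correlation 1 list passed in place of 9, and the other 8 lost their call. The estimate was below the preset 0.01 for MHC class I (-0.050) and the m6A genes (-0.032). For the others that lost their call it ran from 0.011 (cholesterol biosynthesis) to 0.239 (ribosomal proteins). A higher correlation between members therefore does not account for the loss of the MHC class I and m6A calls under this setting. The GC and length correction also ended the calls of ribosomal proteins and of the unfolded protein and integrated stress response, and brought RAS-MAPK output (adjusted p = 0.0281) and hypoxia and glycolysis (adjusted p = 0.0149) past the threshold, both lower. Under it 346 called genes turned direction while 4839 of 7228 kept call and direction. Of named genes, HIST1H2BK was called in the other direction (-0.13, adjusted p = 0.00936), SYNCRIP (0.077) and MT-ND1 (-0.0039) changed sign and lost their calls, and U2SURP, KRT8 and EGFL7 lost theirs. The GC and length correction gave 2718 genes higher and 4035 lower (40.2% higher against 48.7%). It moved the median log2 fold change of all tested genes from -0.004 to -0.049, so falls and turns of direction under it include this shift. With library size alone 2988 genes were higher and 4160 lower, 41.8% higher. Leaving out each library gave 3250 to 3369 higher and 3464 to 3615 lower genes, and HNRNPC values from -3.82 to -3.74. Depth limits weakly expressed genes most.

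The replicate number of the titles could not be used as a block because the columns carry none. With the column suffix as a replicate block 3488 genes were higher, 3671 lower, 220 at least 2-fold higher and 189 at least 2-fold lower, and 9 lists passed. Deviations of libraries with the same suffix correlated at -0.04, 0.01 and -0.04, so the suffixes did not pair the libraries. Settings meant for data without counts did not apply. The list test has no glmTreat form, and that setting was not run for lists or named genes.

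Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 3520 and 3708 genes, with 221 and 187 at least 2-fold changed, and 1 split, the real one, reached each of these counts. The highest of the other splits was 0. Each of those mixes shHNRNPC and shcontrol libraries on both sides, so the difference between the groups adds to the spread and works against calls. Their 0 therefore does not measure chance. For lists the real split gave 9 and the others 1 to 5. With 10 splits the share cannot fall under 0.05.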

Other observations

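The additional gene lists, the leukocyte, shRNA and recombination tests and the GC correction were chosen after the data were examined. The tests of GC content within groups and in single-exon genes were set down before their values were seen, but the comparison of slopes and the bootstrap interval used to judge them were added afterwards.

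Genes that respond to interferon-gamma as well as type I interferon, and a checkpoint ligand, were higher in shHNRNPC. Of 16 tested, 13 rose and 1 fell (median 0.86, camera adjusted p = 5.75e-07 over 6 added lists, and adjusted p = 0.0302 with an estimated correlation). GBP4, a guanylate-binding protein, rose 3.33-fold from 6.70 ± 0.165 to 22.4 ± 1.07 CPM. The chemokines CXCL10 and CXCL11 rose 2.31-fold and 2.42-fold, SOCS1, a feedback inhibitor of cytokine signalling, rose 2.09-fold, and CD274, which encodes PD-L1, rose 2.01-fold at a low level (0.530 to 1.06 CPM, adjusted p = 0.0228). IFNL1, a lambda interferon, rose 3.35-fold from 0.431 to 1.46 CPM. In iron handling, FTL, the ferritin light chain, fell 1.69-fold from 2854 ± 31.1 to 1693 ± 16.3 CPM, TFRC, the transferrin receptor, fell 1.79-fold and IREB2, a regulator of both, fell 1.78-fold, while FTH1 had a log2 fold change of -0.02 (adjusted p = 0.798). Of the 9 iron genes tested 4 fell, ACO1 (1.54-fold) being the other, and 2 rose, SLC11A2 (1.49-fold) and HMOX1 (1.46-fold). The list did not pass (median -0.02, adjusted p = 0.0605).

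Of 71 nuclear-encoded respiratory chain subunits 47 rose and 7 fell (median 0.16, adjusted p = 5.75e-07, and adjusted p = 0.168 with an estimated correlation). This median lay at percentile 94.09 of matched random lists. After the GC and length correction 29 rose and 25 fell, with a median of 0.06 (adjusted p = 0.0591). Of 15 COPI and COPII coat genes, listed because ARCN1 had fallen, 9 fell and 5 rose (adjusted p = 0.0324, and adjusted p = 0.262 with an estimated correlation). Without ARCN1 the unadjusted p was 0.105 (0.0146 after the GC and length correction), and the median lay at percentile 11.22 of matched random lists, so no fall of the list beyond ARCN1 is claimed. Of 25 NRF2 targets 10 rose and 7 fell (adjusted p = 0.455).

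The rise of type I interferon genes could have come from blood cells in the cultures, from the sequence trend or from the hairpin. Of leukocyte transcripts, LYZ, LAPTM5, TYROBP and CD74 together were higher by 0.935 CPM in shHNRNPC, against 9134 CPM for the interferon list. Each stayed under 1 CPM, which argues against leukocyte RNA as the source of the interferon transcripts, since leukocytes would bring all their abundant transcripts. Whether signals from a few such cells acted on the culture was not tested. PTPRC and AIF1, also chosen for this test, are absent from the deposited table and could not be used. CD68, which was not part of the test, rose from 43.2 to 64.9 CPM and was thus already present in shcontrol. The median of the list was 0.83 after the GC and length correction and 0.90 before, which argues against the sequence trend. A response to the hairpin itself cannot be told apart from an effect of HNRNPC loss, since the labels tell apart 1 knockdown construct. A second construct or a rescue would test the hypothesis that loss of HNRNPC raises these genes.

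The trend of fold change with GC content may be technical or biological. Between libraries of 1 group the largest absolute rho with GC content was 0.20, against 0.43 for the fold changes of the group means and 0.337 to 0.456 for single pairs of libraries across the groups. The bound set beforehand, less than 50% of the rho between the groups, is met against the group means. It is also met against the higher single pairs but not against the lower ones, so the rho alone does not decide. The slope of log2 change per 10% of GC was at most 0.034 within groups and at least 0.160 between them, which argues against a bias that varies from library to library as the whole cause. Single-exon genes (292) had a rho of 0.22 (permutation p = 1e-04, 95% bootstrap interval 0.101 to 0.336), against 0.44 in genes with introns. For all single-exon genes that argues, narrowly, against splicing of a gene's own introns as the whole cause, for which a rho under 0.1 had been set beforehand. Exon number was that of the longest coding transcript, so other transcripts of these genes may be spliced. Indirect effects of splicing in other genes were not tested. Without the mitochondrially encoded genes rho was 0.20 in 280 single-exon genes. No interval or p was computed for these, so whether nuclear genes alone stay above 0.1 was not tested. A bias set once per group at library preparation cannot be told apart from an effect of the knockdown, because the labels give no batch that crosses the groups (rho 0.43).

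Genes of homologous recombination and replication fork repair were lower, and the hypothesis that this goes beyond the sequence trend was tested. Of 53 genes 30 fell and 12 rose, among them BRCA2 (log2 fold change -0.95, SE 0.128), BRIP1 (-1.02, SE 0.094) and ATM (-0.77, SE 0.086), with a median of -0.37 (adjusted p = 0.00410, and adjusted p = 0.168 with an estimated correlation). The median lay at percentile 0.06 of 10000 random lists matched on GC content and transcript length, whose own median was -0.15, and at percentile 2.51 without WRN, RAD18 and WRNIP1, which prompted the list. After the correction the median was -0.20 and the call ended (adjusted p = 0.105), as the effect shrank. Part of the fall therefore goes with the trend, and whether the rest exceeds it cannot be told apart here, since the list was written after its genes had been seen.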
